A study of Homo sapiens with 213 samples.

How the data were processed

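The values used are those of the submitters. Per the labels, libraries were made with a 3' tag kit (QuantSeq 3' FWD). The submitters' processing notes give alignment with Bowtie2 2.3.4.1 to GRCh38, read counting per gene with featureCounts of Subread 1.6.2, and DESeq2 1.18.1. The time-course table as deposited holds raw counts of reads per gene, and no scaling by the authors was found in it. The 3 knockout tables as deposited hold log2 values after the variance-stabilising transformation that the authors made with DESeq2. Each table has 58735 gene identifiers, which are those of GENCODE 29, and symbols were taken from that release.

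Time-course counts were fitted with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3, 1 fit per stage, and p-values were adjusted with Benjamini-Hochberg at 0.05. Knockout values were fitted with limma 3.58.1 (empirical Bayes with trend), 1 fit per table and day, over genes at least 1 log2 unit above the table minimum in at least 2 libraries of that day, with the same adjustment. Interaction counts come from an F test of whether the knockout effect differs between types. DESeq2 1.42.0 was run as an alternative. Where a group has 1 library, its spread is taken from the other groups of the fit. P-values at these group sizes rest on spread shared across genes.

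Reads behind the knockout values were recovered by inverting the transformation. In TBX5 and FOXF1 100% of recovered values were whole numbers within 0.02. In the ISL1 table the lowest library had 70.47% and the median library 98.09%, and below 51 reads 100% were whole. The minima that stand for 0 reads are 4.777 (ISL1), 5.737 (TBX5) and 6.128 (FOXF1). A count of 0 allows up to 3 reads, which is 1.17 CPM in the deepest and 2.85 in the shallowest time-course library, 0.92 and 6.86 for ISL1, 1.3 and 4.14 for TBX5 and 0.52 and 1.38 for FOXF1. These limits cover counting error only.

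The comparisons, tests, 26 gene lists (283 genes) and most alternatives were fixed before the data were examined. Lists were tested with camera using the correlation between genes estimated for each list, adjusted over the lists of each comparison. Signatures of the d3.5 and d9.5 types were defined on the time course and tested in the knockouts of the same day, so they are independent of the knockout libraries. Genes are named by a rule: the targeted gene, the largest 6 rises and 4 falls (4 and 4 in knockouts) among genes that passed with libraries of the 2 sides not overlapping and at least 10 CPM in the higher group (2 log2 units above the minimum in knockouts), members of the lists, and 10 genes fixed beforehand. Genes without a symbol, pseudogenes and most noncoding RNAs were left out of the rule, and not all genes it yields are printed. With 3 against 3 libraries, 10% of genes do not overlap by chance.

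A library titled as TBX5 WT AVC d9.5 has a header that reads TBX5 KO AVC d3.5, and was left out of every reported fit for that reason alone. Its mean correlation over 2000 genes was 0.982 with TBX5 KO AVC d3.5 and 0.552 with the other library of its titled group. A library titled 4OFT at d5.5 was taken as OFT. No label names a library series. In the time course it is a split of the library numbers in titles, fixed beforehand, and in TBX5 at d9.5 it was drawn from those numbers after seeing the data, with no gap between the 2 runs. There are 5 FOXF1 columns that match no sample and were not used. Titles and headers number TBX5 KO AVC d3.5 libraries differently.

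Lowest correlations between 2 replicates were 0.915 (time course, Atria d9.5), 0.926 (ISL1, KO OFT d9.5), 0.801 (TBX5, KO LV d9.5) and 0.879 (FOXF1, WT Atria d9.5). No 2 libraries were identical among 99 pairs of replicates in the time course, 46 in ISL1, 30 in TBX5 and 21 in FOXF1, and the lowest chi-square per degree of freedom was 1.79. Replicate numbers were not used as pairs in the reported fits.

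What the tests find was measured on libraries simulated from the fitted means and spread, with changes of known size put in. In d9.5 LV, 2-fold changes were found for 90% of 100 genes and 4-fold for 100%, with 10 false calls of 12085. Differences of 0.5 and 1 log2 unit were found for 44% and 96% in ISL1 RV d9.5, 28% and 82% in TBX5 LV d9.5 and 22% and 86% in FOXF1 FHF d3.5, with 5, 7 and 4 false calls.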

Results

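The data are 3' tag RNA sequencing of human cardioids, self-organising heart models grown from the pluripotent WTC line and patterned towards left ventricle (LV), right ventricle (RV), outflow tract (OFT), atrioventricular canal (AVC) and atria. The time course has 99 libraries in 33 groups of 3, from pluripotent cells through d1.5 mesoderm and d3.5 progenitors to d14, at 1053785 to 2554199 counted reads each (median 1816242). A further 114 libraries compare ISL1, TBX5 or FOXF1 knockout (KO) with wild type (WT) at d3.5 and d9.5, with 1 to 3 libraries per group. Read totals recovered from those tables run from 437482 to 3270422 for ISL1, 724809 to 2311056 for TBX5 and 2180218 to 5751933 for FOXF1.

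Time-course values are log2 fold changes ± error from edgeR, then mean CPM (reads scaled to a common library size) in the named against the comparison group. Levels near 0 CPM rest on few reads, and this error is too small there. Contrasts against several groups use the mean of their log levels, while the CPM after "against" is the plain mean over the same libraries. Knockout values are limma differences in units of the variance-stabilised log2 scale, which are smaller than log2 fold changes at low counts, with CPM from recovered reads in KO against WT. A gene rose or fell where its Benjamini-Hochberg adjusted p was under 0.05. List results give the genes that rose and fell of those measured, the same adjusted over the list alone where it differs, the median change and the camera adjusted p over lists. These p-values measure the spread between these libraries, which the design text describes as 3 biological and 8 technical replicates per time point. n is 3 per group unless stated.

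**Figure D1:**
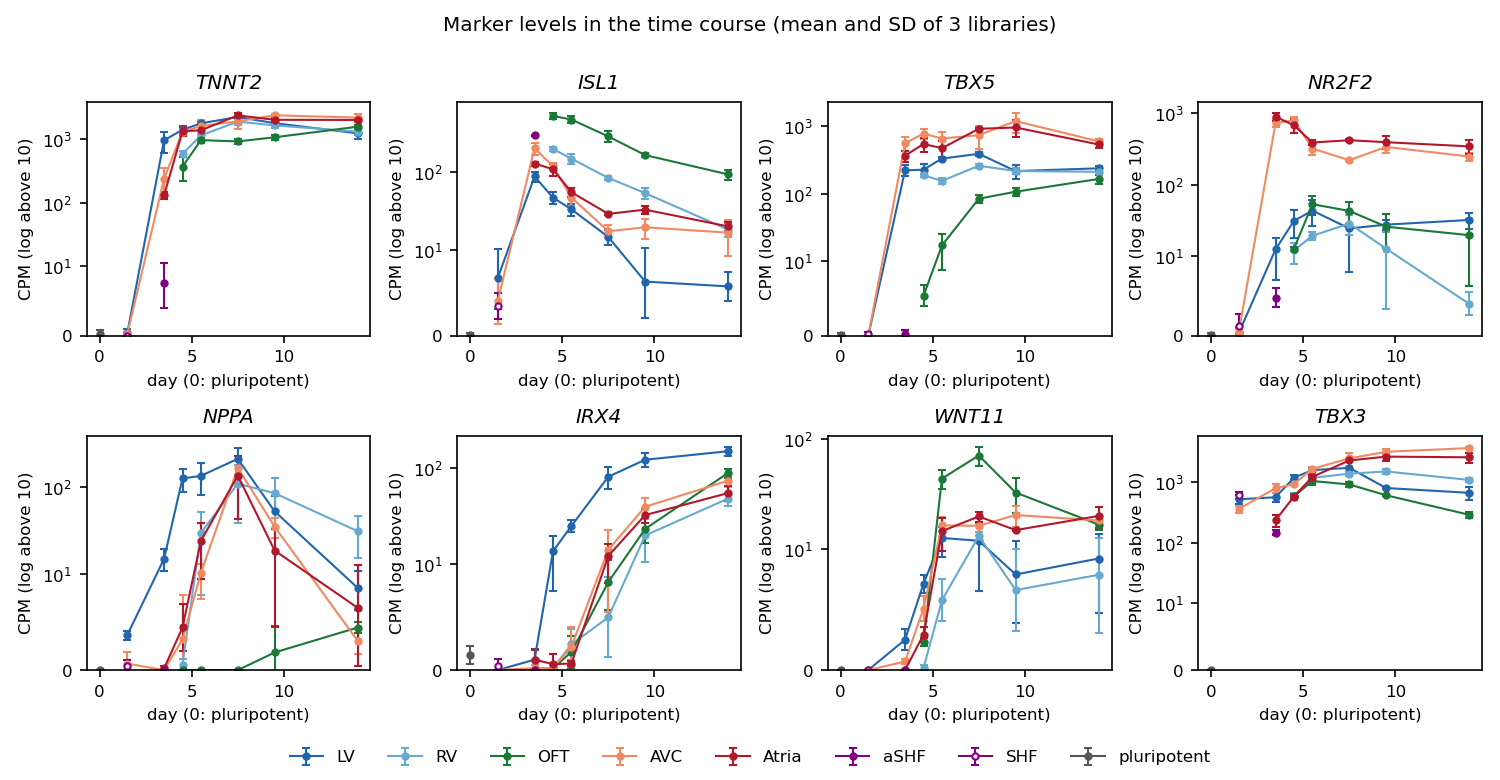
Mean CPM of marker genes by day and cardioid type in the time course, 3 libraries per point. TNNT2 reached 2403 CPM in AVC cardioids at d9.5, and NR2F2 890 CPM in Atria progenitors at d3.5.

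Induction turned on mesoderm transcription factors. Against pluripotent cells, EOMES stood at 1161 against 0 CPM, TBX3 at 502 against 0 CPM and GATA6 at 253 against 0 CPM, and LHX1 rose by 14.04 ± 0.21 (3324 against 0.142 CPM). The neuronal pentraxin NPTX1 fell (-10.85 ± 0.53, 0.0435 against 191 CPM) and the calcium sensor VSNL1 (-8.50 ± 0.47, 0.0456 against 37 CPM). Of 11643 genes, 5866 passed, 2820 higher and 3046 lower. The primitive streak list (7 up, 0 down of 7, median 8.79, p 4.48e-05) and canonical WNT targets (7 up, 0 down of 9, median 7.27, p 0.000165) rose, with GSC, MIXL1, TBXT and SP5 among them. Pluripotency genes fell (0 up, 7 down of 9, median -1.35, p 0.000165), (-7.20) for SOX2 and -3.32 for NANOG but -1.78 for POU5F1. HAND1 (20.9 against 0 CPM) and FOXF1 (7.78 against 0 CPM) were listed at 0 in pluripotent cells, and ISL1 rose by 4.52 ± 0.89 (4.74 against 0.142 CPM).

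The 3 mesoderm types were close to each other at d1.5. LV minus SHF gave 0 genes in edgeR and 0 in DESeq2, with 560 at an unadjusted p under 0.05, and 1 gene without LV replicate 2. AVC minus SHF gave 18 genes, 7 higher and 11 lower, led by the BMP-responsive MSX1 at -2.06 ± 0.17, 57.2 against 241 CPM. The WNT antagonist DKK1 fell (-1.07 ± 0.13, 143 against 299 CPM), and WNT targets moved as a list (0 up, 4 down of 9, alone 0 and 5, median -0.93, p 8.98e-05). MSX1 and DKK1 passed with each library left out in turn, the other genes of this comparison named by size did not. In a fit on all 99 libraries DKK1 (-1.08) did not pass either. This count was 9 without SHF replicate 2, 5 without SHF replicate 3, 5 without AVC replicate 1 and 7 without AVC replicate 3. It was 44 without the filter and 36 with a library series term. LV minus AVC gave 7 genes, all higher, again with MSX1 at 1.71 ± 0.17, 191 against 57.2 CPM and with WNT targets as a list (2 up, 0 down of 9, alone 4 and 0, median 0.57, p 0.00345). This count was 1 without AVC replicate 1, 4 without AVC replicate 2, 2 without AVC replicate 3 and 18 without LV replicate 1. It was 16 with DESeq2 and 62 without the filter.

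LV progenitors at d3.5 already carried a contractile programme that the other 3 progenitors mostly lacked. The muscle LIM protein CSRP3 rose by 9.79 ± 0.40 (149 against 0.444 CPM), the natriuretic peptide NPPB by 9.65 ± 0.15 (936 against 3.65 CPM) and the phosphatase inhibitor PPP1R14C by 8.26 ± 0.30 (93.5 against 0.275 CPM). SMPX (55.6 against 0 CPM) and ABRA (17.6 against 0 CPM) were listed at 0 elsewhere. TNNT2 rose by 4.08 ± 0.21 (966 against 125 CPM), HAND1 by 4.51 ± 0.30 (82.3 against 6.55 CPM) and NPPA by 7.27 ± 0.64 (14.8 against 0.0569 CPM). The orphan receptors NR2F1 (-6.26 ± 0.24, 2.11 against 402 CPM) and NR2F2 (-3.46 ± 0.23, 12.5 against 540 CPM) fell, as did SOX3 (-6.02 ± 0.91, 0.172 against 32.7 CPM), and EYA1 stood at 0 against 15.9 CPM. ISL1 was lower (-1.08 ± 0.13, 88.2 against 211 CPM). TBX5 was 2.45 above the mean of log levels although its plain mean was lower (222 against 309 CPM), because aSHF progenitors held almost none. Of 11955 genes 3780 passed, 2140 higher and 1640 lower.

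Lists followed the single genes. Sarcomere (16 up, 0 down of 16, median 5.19, p 2.86e-05) rose through CSRP3, MYOM1 (7.44) and ACTC1 (7.28). Calcium handling (8 up, 0 down of 8, median 3.22, p 2.34e-05) rose through PLN and SLC8A1, and the first heart field list (5 up, 1 down of 6, median 2.76, p 0.00357) through HAND1 and NKX2-5 (3.09). Glycolysis and hypoxia genes (11 up, 0 down of 11, median 1.11, p 0.00298) rose too, with PDK1 at 2.92. The posterior second heart field list fell (2 up, 5 down of 10, median -1.45, p 0.0101).

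In anterior second heart field progenitors (aSHF) EBF2 (48.7 against 0 CPM), PAX1 (17.1 against 0 CPM) and FOXI2 (12.7 against 0 CPM) were listed at 0 in the other progenitors, and NKX2-3 rose by 7.29 ± 0.46 (39.9 against 0.296 CPM), the retinoic acid hydroxylase CYP26C1 by 7.37 ± 0.65 (20 against 0.109 CPM) and VGLL2 by 6.68 ± 0.63 (19.2 against 0.172 CPM). TBX5 fell (-9.81 ± 0.38, 0.278 against 383 CPM), while PLN (0 against 173 CPM) and MYBPC3 (0 against 131 CPM) were at 0. TNNT2 (-5.38 ± 0.35, 7.57 against 445 CPM), NR2F2 (-5.36 ± 0.23, 4.79 against 542 CPM) and FOXF1 (-3.96 ± 0.38, 4.02 against 92.4 CPM) fell and ISL1 rose by 1.16 ± 0.11 (300 against 140 CPM). Of 2090 genes that passed, 950 were higher and 1140 lower. The anterior second heart field list rose (8 up, 2 down of 10, median 3.57, p 0.000116) with TBX1 at 8.84 against 0 CPM and FGF10 at 4.15. First heart field (0 up, 6 down of 6, median -2.36, p 0.000111), atrial (0 up, 7 down of 8, median -3.15, p 0.000111) and sarcomere genes (0 up, 12 down of 16, median -2.57, p 0.00106) fell. Ventricular genes were higher (3 up, 0 down of 6, median 0.70, p 0.0139, 0.108 without the filter), and the atrioventricular canal list was lower (2 up, 6 down of 10, median -1.01, p 0.0139).

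Posterior second heart field genes were higher in Atria progenitors. NR2F1 rose by 5.01 ± 0.13 (839 against 123 CPM) and the potassium channel KCNA5 by 3.85 ± 0.26 (123 against 23 CPM). NR2F2 (4.62 ± 0.13, 890 against 247 CPM), FOXF1 (2.91 ± 0.23, 142 against 46.2 CPM) and TBX5 (3.28 ± 0.21, 367 against 261 CPM) rose, while HAND1 (-3.81 ± 0.59, 1.28 against 33.6 CPM) and TBX3 (-0.80 ± 0.14, 237 against 505 CPM) fell. HHEX fell (-3.68 ± 0.40, 3.49 against 60 CPM) and the receptor kinase ERBB4 (-3.07 ± 0.27, 4.37 against 53.4 CPM). 1343 genes passed, 622 higher and 721 lower. The posterior second heart field list (8 up, 0 down of 10, alone 8 and 2, median 2.76, p 3.46e-06) and the HOX list (7 up, 0 down of 7, median 1.95, p 0.000867) rose, as did retinoic acid response (5 up, 0 down of 9, alone 6 and 0, median 1.45, p 0.000867) with CYP26A1 and CYP26B1. Sarcomere genes were lower (0 up, 9 down of 16, alone 1 and 11, median -1.38, p 0.0169).

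AVC progenitors were higher in the posterior second heart field list and in endoderm transcripts. Fibrinogen FGB rose by 8.24 ± 0.42 (275 against 8.79 CPM), the apolipoprotein APOA1 by 5.42 ± 0.46 (82 against 6.9 CPM), AFP by 5.33 ± 0.62 (21.8 against 0.947 CPM) and HNF4A by 4.23 ± 0.60 (15.6 against 2.2 CPM), with TTR at 4.69 ± 0.34, 31.7 against 2.43 CPM. NR2F2 (4.2 ± 0.13, 724 against 302 CPM), TBX5 (4.08 ± 0.20, 560 against 197 CPM), FOXF1 (2.59 ± 0.24, 122 against 53.2 CPM) and TBX3 (1.51 ± 0.12, 800 against 318 CPM) rose, and NPPA was at 0 against 5 CPM. COL8A1 (-4.08 ± 0.60, 0.518 against 10.1 CPM), LHX1 (-3.12 ± 0.21, 19.4 against 234 CPM), and the YAP target CYR61 (-2.88 ± 0.21, 8.07 against 93.7 CPM) fell. 1137 genes passed, 625 higher and 512 lower. This count was 753 without AVC replicate 1. Posterior second heart field (8 up, 0 down of 10, alone 9 and 0, median 2.94, p 7.38e-06), first heart field (4 up, 0 down of 6, alone 5 and 1, median 1.32, p 0.000146), HOX (7 up, 0 down of 7, median 2.71, p 0.00102) and endoderm genes (9 up, 0 down of 10, alone 10 and 0, median 2.78, p 0.00429) rose. Ventricular genes were lower (0 up, 3 down of 6, alone 0 and 4, median -1.22, p 0.0131), IRX2 (-2.25) and IRX1 (-1.91).

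At d4.5 RV and OFT cardioids had parted along retinoic acid and BMP genes. TBX5 rose in RV by 5.17 ± 0.26 (188 against 5.34 CPM) and the retinol acyltransferase LRAT by 6.48 ± 0.40 (67.4 against 0.723 CPM), and DUSP9 (13.3 against 0 CPM) and NR0B1 (10.9 against 0 CPM) were listed at 0 in OFT. The receptor subunit GABRB2 (7.08 ± 0.65, 32.1 against 0.18 CPM) and FOXF1 (3.31 ± 0.51, 19.1 against 1.96 CPM) were higher as well. OFT was higher in CBLN2 (-5.22 ± 0.80, 0.298 against 15.1 CPM), the hedgehog antagonist HHIP (-4.42 ± 0.70, 0.813 against 19.7 CPM) and the channel KCNMA1 (-4.16 ± 0.69, 0.946 against 19.5 CPM), and in HAND1 (-3.86 ± 0.45, 3.05 against 43.8 CPM) and ISL1 (-1.36 ± 0.14, 199 against 531 CPM). Of 12279 genes 987 passed, 530 higher in RV and 457 higher in OFT. This count was 650 without OFT replicate 3, 631 without RV replicate 1 and 646 without RV replicate 2. Retinoic acid response was higher in RV (4 up, 0 down of 9, alone 5 and 0, median 2.3, p 0.00148) with CYP26A1 at 4.71 and DHRS3 at 4.39. BMP targets (1 up, 8 down of 10, alone 1 and 9, median -0.92, p 0.00417) and outflow tract genes (1 up, 6 down of 9, median -1.36, p 0.00297) were higher in OFT, with MSX1 at -2.17 and BMP4 at -2.43.

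LV cardioids at d9.5 were marked by the ventricular factor IRX4 (2.13 ± 0.19, 122 against 28.5 CPM) and by secreted proteins typical of liver and yolk sac. AHSG rose by 7.07 ± 0.44 (222 against 22.9 CPM), the protease inhibitor SERPINA1 by 5.54 ± 0.41 (40.1 against 5.79 CPM) and transferrin TF by 4.07 ± 0.29 (102 against 11.8 CPM). MSX2 (-3.16 ± 0.22, 50.9 against 484 CPM), TBX2 (-3.04 ± 0.24, 12.7 against 138 CPM) and ISL1 (-2.93 ± 0.28, 6.3 against 68.1 CPM) fell, as did NR2F2 (-1.56 ± 0.28, 27.6 against 191 CPM), TBX3 (-1.07 ± 0.12, 809 against 2010 CPM) and TBX5 (-0.91 ± 0.20, 217 against 622 CPM). 1038 genes passed, 644 higher and 394 lower. This count was 619 without LV replicate 1 and 673 without LV replicate 2. Ventricular genes rose (6 up, 0 down of 9, alone 8 and 0, median 0.89, p 0.00034), HEY2 by 2.74 and MYH7 by 1.70, and so did endoderm (4 up, 0 down of 6, alone 5 and 0, median 2.89, p 0.00533) and cell cycle genes (10 up, 0 down of 13, alone 12 and 0, median 1.11, p 0.00533). BMP targets (0 up, 6 down of 10, median -0.55, p 0.000444), WNT targets (0 up, 4 down of 6, median -0.84, p 0.00131) and atrioventricular canal genes (0 up, 5 down of 10, median -0.67, p 0.000635) were lower.

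RV cardioids were low in transcripts of dividing cells. All 13 cell cycle genes measured fell (0 up, 13 down of 13, median -2.11, p 0.000866), AURKB (-3.04) and UBE2C (-2.50), and CDCA8 fell (-3.69 ± 0.59, 1.17 against 16.8 CPM). The immediate early gene FOS rose by 4.60 ± 0.41 (32.9 against 2.06 CPM) and the potassium channel KCNQ3 by 3.51 ± 0.41 (44 against 5.83 CPM). RSPO3, a WNT agonist, fell (-6.60 ± 0.40, 1.48 against 186 CPM) and GNG2 (-3.69 ± 0.67, 0.57 against 10.1 CPM). NPPA (2.43 ± 0.37, 84.6 against 26.8 CPM) and ISL1 (0.90 ± 0.20, 53.8 against 56.3 CPM) rose, while HAND1 (-2.88 ± 0.36, 5.17 against 50.4 CPM), NR2F2 (-2.95 ± 0.32, 12.8 against 195 CPM) and TBX5 (-0.89 ± 0.20, 218 against 622 CPM) fell. 1099 genes passed, 545 higher and 554 lower. This count was 609 without RV replicate 1, 607 without RV replicate 2 and 664 without RV replicate 3. Ventricular genes rose (5 up, 1 down of 9, median 0.62, p 0.000866), IRX1 by 2.98 and IRX2 by 1.57, and atrioventricular canal genes fell (0 up, 7 down of 10, alone 1 and 7, median -1.17, p 0.000866).

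Compared directly, LV exceeded RV in IRX4 (2.60 ± 0.28, 122 against 19.7 CPM) and HAND1 (2.52 ± 0.41, 29.9 against 5.17 CPM), while ISL1 (-3.07 ± 0.31, 6.3 against 53.8 CPM), FOXC1 (-3.35 ± 0.63, 1.77 against 18.9 CPM) and TBX3 (-0.92 ± 0.14, 809 against 1521 CPM) were lower. AFP (438 against 0 CPM), AHSG (222 against 0 CPM), APOA2 (67.2 against 0 CPM), FGB (65.6 against 0 CPM) and SERPINA1 (40.1 against 0 CPM) were listed at 0 in RV. 573 genes passed, 389 higher and 184 lower. This count was 354 without RV replicate 3. Cell cycle genes were higher in LV (12 up, 0 down of 13, alone 13 and 0, median 2.46, p 0.000379), CCNA2 by 3.68, and the anterior second heart field list was lower (0 up, 2 down of 8, alone 0 and 4, median -1.18, p 0.00224).

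OFT cardioids kept ISL1 (2.89 ± 0.17, 166 against 28.1 CPM) and WNT11 (1.51 ± 0.26, 32.6 against 12.4 CPM) high and muscle genes low. CDC20B was at 86.2 against 0 CPM, the leukotriene receptor CYSLTR2 rose by 7.21 ± 0.60 (22.5 against 0.29 CPM) and the WNT agonist RSPO2 by 5.67 ± 0.29 (84.3 against 17.8 CPM). Troponin TNNI3 (0 against 63.4 CPM) and MTTP (0 against 13.5 CPM) were listed at 0, and leiomodin LMOD2 fell (-7.15 ± 0.42, 0.362 against 63.2 CPM). FOXF1 (-5.49 ± 0.68, 0.207 against 11.9 CPM), NPPA (-4.57 ± 0.67, 1.83 against 47.5 CPM), TBX5 (-2.22 ± 0.22, 107 against 650 CPM), NR2F2 (-1.72 ± 0.28, 25.9 against 192 CPM) and TNNT2 (-0.90 ± 0.11, 1079 against 1978 CPM) fell, while HAND1 rose by 1.80 ± 0.24 (72 against 33.7 CPM). 1664 genes passed, 825 higher and 839 lower. This count was 1081 without OFT replicate 3 and 1097 without OFT replicate 1. Outflow tract (8 up, 0 down of 9, median 2.55, p 3.34e-06), cell cycle (11 up, 0 down of 13, alone 13 and 0, median 1.12, p 0.0139) and mesenchyme genes (4 up, 1 down of 7, median 1.32, p 0.015) rose, WNT5A by 3.76 and BMP4 by 3.16. Sarcomere (0 up, 14 down of 18, median -0.71, p 0.00164) and atrial genes (1 up, 7 down of 11, alone 1 and 9, median -1.72, p 0.00843) fell.

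AVC cardioids had the highest mean TBX3 of the 5 types (1.46 ± 0.10, 3225 against 1406 CPM) together with TBX5 (2.21 ± 0.16, 1199 against 376 CPM), NR2F2 (2.98 ± 0.20, 336 against 114 CPM) and HAND1 (2.22 ± 0.23, 87.9 against 29.7 CPM). GDF10 rose by 5.80 ± 0.31 (71.3 against 7.25 CPM), the neuronal STMN2 by 4.84 ± 0.52 (16.6 against 1.05 CPM) and IGFBP6 by 4.18 ± 0.21 (144 against 16.4 CPM). IRX1 fell (-3.74 ± 0.26, 6.92 against 137 CPM), and TNNT2 rose by 0.61 ± 0.10 (2403 against 1646 CPM). 990 genes passed, 623 higher and 367 lower. This count was 540 without AVC replicate 1 and 579 without AVC replicate 2. The atrioventricular canal list rose (8 up, 0 down of 10, median 1.46, p 2.76e-05), RSPO3 by 3.26 and TBX2 by 2.27, as did atrial (6 up, 0 down of 11, median 1.65, p 0.000986) and endoderm genes (6 up, 0 down of 6, median 3.64, p 0.00144). Ventricular genes were lower (0 up, 3 down of 9, alone 2 and 4, median -0.23, p 0.00133).

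In Atria cardioids TBX5 (1.81 ± 0.17, 964 against 435 CPM), TBX3 (1.12 ± 0.10, 2682 against 1542 CPM), NR2F2 (3.25 ± 0.20, 391 against 101 CPM) and KCNJ3, a potassium channel of atrial muscle (3.89 ± 0.38, 21.6 against 3.51 CPM), were higher than the mean of the other 4 types. Atria was not tested against AVC directly. The dopamine receptor DRD1 rose by 4.60 ± 0.51 (13.1 against 1.95 CPM), PDGFB by 1.91 ± 0.38 (20.2 against 6.79 CPM) and FOXF1 by 1.97 ± 0.36 (15.9 against 7.96 CPM). The cadherin CDH11 (-2.53 ± 0.28, 5.48 against 50.3 CPM) and endomucin EMCN (-2.74 ± 0.59, 1.28 against 12.6 CPM) fell. 805 genes passed, 519 higher and 286 lower. This count was 427 without Atria replicate 1 and 407 without Atria replicate 3. Atrioventricular canal (7 up, 0 down of 10, alone 8 and 0, median 1.16, p 5.02e-05), posterior second heart field (4 up, 0 down of 6, alone 5 and 0, median 1.84, p 5.98e-05) and atrial genes (5 up, 0 down of 11, alone 8 and 0, median 0.72, p 0.000354) rose. Endoderm transcripts summed over the endoderm list were 593 CPM in LV, 472 in AVC and 180 in Atria at d9.5 against 32.2 in RV and 16.5 in OFT.

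**Figure D2:**
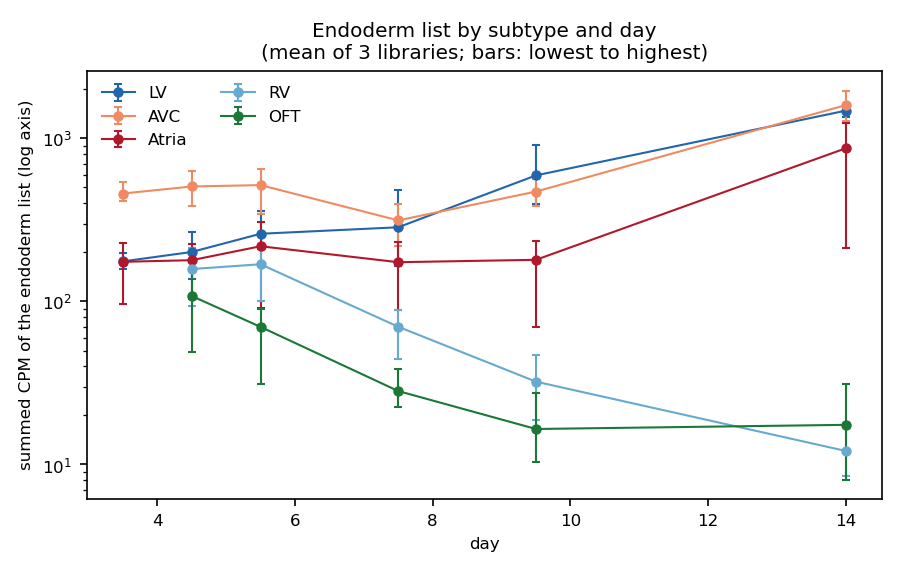
Summed CPM of the endoderm list by day and cardioid type, 3 libraries per point. At d14 the sums ran from 12.1 CPM in RV to 1600 in AVC.

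From d7.5 to d14, averaged over the 5 types (n = 15 per day), nephronectin NPNT rose by 5.08 ± 0.25 (48.7 against 2.11 CPM), IGFBP5 by 3.15 ± 0.11 (974 against 131 CPM) and IRX4 by 2.33 ± 0.14 (82.7 against 24 CPM). The RNA-binding LIN28A fell (-5.26 ± 0.20, 3.28 against 88.3 CPM), tenascin TNC (-3.53 ± 0.27, 3.28 against 30.2 CPM) and SPRY4 (-3.38 ± 0.27, 2.44 against 17.8 CPM). ISL1 (-1.25 ± 0.12, 30.9 against 87 CPM), HAND1 (-1.52 ± 0.18, 29.8 against 61.3 CPM) and NR2F2 (-0.82 ± 0.16, 129 against 146 CPM) fell, with smaller falls of TBX5 (-0.32) and TNNT2 (-0.22). With a term for the library series these ended at -0.23 and -0.13 without passing. NPPA was at 10.7 against 124 CPM and FOXF1 at 5.76 against 7.59 CPM, neither passing. Of 13672 genes 6867 passed, 3622 higher and 3245 lower. The anterior second heart field list (0 up, 7 down of 8, median -1.11, p 0.000684), pluripotency genes (0 up, 4 down of 6, median -1.57, p 0.00309) and sarcomere genes (1 up, 13 down of 18, median -0.64, p 0.00389) fell, MYL3 (-1.79) and MYL7 (-1.28). Summed endoderm transcripts were 285 CPM at d7.5 and 1480 at d14 in LV, 314 and 1600 in AVC, 174 and 870 in Atria, 69.9 and 12.1 in RV and 28.2 and 17.5 in OFT. In the cell cycle list 11 of 13 genes rose, BIRC5 by 1.28, without a list call (p 0.314).

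Marker levels by day were described without a test. TNNT2 was 966 CPM in LV and 7.57 in aSHF at d3.5, up to 2396 at d7.5 (Atria), and 1247 to 2210 over the 5 types at d14. NPPA was highest at d7.5 in LV (210 CPM), AVC (166), Atria (135) and RV (109), with 0 in OFT, and stood at 30.9 CPM in RV and under 9 in the other 4 types at d14. IRX4 first passed 10 CPM in LV at d4.5 (13.5) and was 149 CPM there at d14 against 47.8 in RV. ISL1 was highest in OFT from d4.5 (531 CPM) to d14 (93.8). FOXF1 was 142 CPM in Atria and 122 in AVC progenitors at d3.5 and 16.0 and 15.3 one day later. TBX3 in AVC reached 3709 CPM at d14 against 292 in OFT.

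Across the 16 time-course comparisons the lists were called as follows, higher then lower, and 29 of these 119 calls did not hold with each library left out. Atrioventricular canal 7 and 5, posterior second heart field 5 and 4, outflow tract 5 and 4, BMP targets 5 and 6, canonical WNT targets 5 and 3, atrial 4 and 3, endoderm 4 and 0, ventricular 3 and 3, anterior second heart field 3 and 3, calcium handling 3 and 3, retinoic acid 3 and 3. First heart field had 3 and 1, HOX 3 and 1, cell cycle 3 and 2, sarcomere 2 and 4, glycolysis and hypoxia 2 and 2, mesenchyme 2 and 0, p53 targets 2 and 0. Pluripotency had 1 and 3, primitive streak 1 and 0, neural 1 and 0, endothelial 1 and 0, NODAL 0 and 1, and fatty acid oxidation 0 and 0 with a smallest p of 0.188. The cardiopharyngeal and the epicardial lists had too few measured genes for a list test in this series of comparisons.

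**Figure D3:**
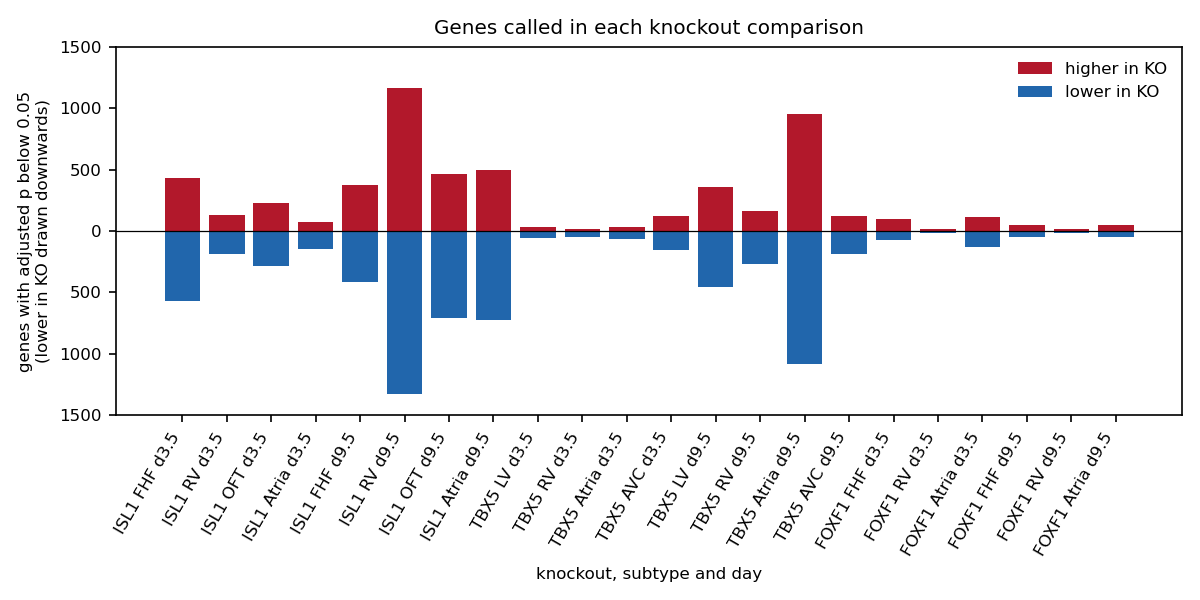
Genes that rose and fell in each knockout comparison. The counts run from 28 for FOXF1 RV d3.5 to 2490 for ISL1 RV d9.5.

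ISL1 itself was read in every ISL1 library. Mean CPM at d3.5 follows. RV had 246 (227 to 259, n = 3) in WT and 293 (256 to 352, n = 3) in KO. OFT had 390 (363 to 413, n = 3) in WT and 275 (251 to 294, n = 3) in KO. Atria had 161 (154 to 174, n = 3) in WT and 93 (80.4 to 102, n = 3) in KO. FHF had 89.7 (68.8 to 106, n = 3) in WT and 227 (199 to 280, n = 3) in KO. Means at d9.5 follow. RV had 65.2 (54.2 to 71.3, n = 3) in WT and 380 (344 to 417, n = 3) in KO. Atria had 26.1 (25.4 to 26.4, n = 3) in WT and 85.2 (80.8 to 92.7, n = 3) in KO. FHF had 10.8 (9.83 to 12.4, n = 3) in WT and 52.9 (45.7 to 62.1, n = 3) in KO. OFT had 155 (75.3 to 235, n = 2) in WT and 290 (254 to 322, n = 3) in KO. The libraries count 3' ends, and where the deletion lies is not given in the sources used here, so these levels do not check the knockout. FHF denotes the first heart field cardioids that form the LV.

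FHF progenitors labelled ISL1 knockout gained posterior second heart field and HOX genes at d3.5. The natriuretic peptide NPPB fell (-2.19 ± 0.17, 215 against 849 CPM), the guidance cue SLIT2 (-2.43 ± 0.14, 115 against 582 CPM) and PPP1R12B (-2.23 ± 0.16, 183 against 798 CPM). Collagen COL3A1 rose by 2.48 ± 0.15 (221 against 19.7 CPM), the zinc finger gene ZIC1 by 2.19 ± 0.12 (70 against 0.248 CPM) and the heat shock gene HSPA1A by 1.91 ± 0.11 (190 against 33 CPM). FOXF1 rose by 0.85 ± 0.14 (34.9 against 7.86 CPM) and NPPA fell (-0.65 ± 0.11, 8.02 against 23.7 CPM). 1003 of 9847 genes passed, 433 higher and 570 lower. Glycolysis and hypoxia genes fell (1 up, 9 down of 11, median -0.90, p 0.000851), LDHA (-1.71) and SLC2A1 (-1.45). Posterior second heart field (5 up, 0 down of 9, median 0.42, p 0.00518) and HOX genes (4 up, 0 down of 6, median 0.79, p 0.00737) rose, WNT2 by 1.24 and HOXB5 by 1.08. Endoderm transcripts summed to 96.3, 82.0 and 130 CPM in WT and 17.0, 25.0 and 22.2 in KO libraries.

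In RV progenitors the protease inhibitor SPINK5 rose by 1.86 ± 0.11 (78.3 against 4.04 CPM), the iron exporter SLC40A1 by 1.39 ± 0.16 (362 against 131 CPM), HSPA1A by 1.32 ± 0.11 (84.6 against 16.7 CPM) and TBX3 by 1.07 ± 0.14 (219 against 93.6 CPM). The proteoglycan VCAN fell (-1.66 ± 0.14, 513 against 1455 CPM), the muscle co-activator MYOCD (-1.47 ± 0.18, 22.2 against 113 CPM) and BMP4 (-1.36 ± 0.22, 89.9 against 265 CPM). 323 genes passed, 134 higher and 189 lower, and no list was called. OFT progenitors lost BMP4 (-2.93 ± 0.22, 73.4 against 608 CPM), the semaphorin receptor NRP2 (-1.77 ± 0.19, 24.2 against 145 CPM) and MEG3 (-1.99 ± 0.10, 0.172 against 59.9 CPM), and gained ZIC1 (3.53 ± 0.12, 216 against 0.144 CPM), SPINK5 (1.89 ± 0.11, 77.5 against 3.26 CPM), TCF4 (1.86 ± 0.14, 1178 against 349 CPM) and FOXC2 (1.86 ± 0.16, 669 against 201 CPM). TBX5 rose there by 0.85 ± 0.13 (15.2 against 0.734 CPM). 516 genes passed, 230 higher and 286 lower. The outflow tract list fell (0 up, 5 down of 6, alone 1 and 5, median -1.13, p 0.000403), HAND2 (-1.70).

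Atria progenitors lost SHISA2 (-1.87 ± 0.13, 39.5 against 204 CPM), the transcription factor MEF2C (-1.50 ± 0.17, 69.1 against 226 CPM), the Notch ligand JAG1 (-1.49 ± 0.12, 77.6 against 244 CPM) and TNNT2 (-0.88 ± 0.17, 38.7 against 93.8 CPM). ZIC1 (2.16 ± 0.12, 73.3 against 0.435 CPM), HSPA1A (1.45 ± 0.11, 70 against 9.23 CPM), IRX1 (1.19 ± 0.12, 84.9 against 21.9 CPM) and NFIA (0.91 ± 0.13, 77.8 against 28.4 CPM) rose. 224 genes passed, 76 higher and 148 lower. It was 143 on the 2 groups alone. Outflow tract (0 up, 4 down of 6, median -0.61, p 0.00133), glycolysis and hypoxia (0 up, 5 down of 11, median -0.28, p 0.00334), calcium handling (0 up, 3 down of 8, alone 0 and 5, median -0.37, p 0.00334), first heart field (0 up, 1 down of 6, alone 0 and 3, median -0.34, p 0.00821) and anterior second heart field genes (1 up, 4 down of 10, alone 3 and 5, median -0.11, p 0.0107) fell, PLN (-1.09) and VEGFA (-0.90). The atrial list (0 up, 2 down of 8, alone 1 and 2, median -0.11, p 0.0495 and up to 0.154 with 1 library left out, 0.0884 without the filter) and the AVC (3 up, 15 down of 46, alone 4 and 21, median -0.26, p 0.00334) and LV progenitor signatures (0 up, 16 down of 50, alone 0 and 20, median -0.24, p 0.0495 and up to 0.0926 with 1 library left out, 0.0562 without the filter) fell. Over the 4 types 735 genes had a knockout effect that differed between types, among them ISL1 (8.88e-10), TBX5 (3.28e-06) and TBX3 (0.000325, adjusted p each).

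At d9.5 FHF cardioids of the ISL1 knockout gained BMP targets. ID4 rose by 2.36 ± 0.25 (502 against 90.6 CPM), fibronectin FN1 by 2.17 ± 0.25 (1601 against 395 CPM), HSPA1A by 2.39 ± 0.22 (174 against 12.4 CPM) and HAND1 by 0.80 ± 0.15 (68.7 against 27.8 CPM), and ZIC1 stood at 110 against 0 CPM. Periostin POSTN fell (-2.20 ± 0.18, 5.73 against 116 CPM), PPP1R12B (-2.08 ± 0.18, 424 against 1573 CPM), FHL2 (-1.92 ± 0.26, 224 against 783 CPM) and myoglobin MB (-1.77 ± 0.22, 218 against 672 CPM). 789 genes passed, 377 higher and 412 lower. This count was 518 without KO FHF replicate 1 and 452 without WT FHF replicate 2. It was 1240 on the 2 groups alone. BMP targets rose (7 up, 0 down of 10, alone 9 and 0, median 0.77, p 0.00697), MSX2 by 1.51. The LV signature of the time course fell (2 up, 18 down of 41, alone 3 and 23, median -0.45, p 0.00697) and the AVC signature rose (19 up, 5 down of 50, alone 23 and 5, median 0.39, p 0.0119). The LV signature includes endoderm genes such as AFP, APOB and TF, and the endoderm list summed to 58.1, 30.9 and 127 CPM in WT and 23.7, 13.7 and 25.1 in KO libraries.

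The largest count of the ISL1 series came from RV at d9.5, where 2490 genes passed, 1165 higher and 1325 lower. FHL2 fell (-4.32 ± 0.26, 32.3 against 857 CPM), myosin light chain MYL3 (-3.44 ± 0.24, 53.7 against 656 CPM), actinin ACTN2 (-3.21 ± 0.19, 107 against 902 CPM) and MB (-3.16 ± 0.22, 41.9 against 474 CPM), and TNNT2 fell (-0.92 ± 0.16, 751 against 1247 CPM). TOP2A rose by 3.99 ± 0.40 (453 against 6.98 CPM), COL3A1 by 3.77 ± 0.24 (1109 against 73.9 CPM) and KCNJ3 by 3.06 ± 0.13 (174 against 1.38 CPM), and NR2F2 rose by 2.19 ± 0.32 (140 against 8.91 CPM). All 18 sarcomere genes fell although the list test did not pass (0 up, 18 down of 18, median -1.68, p 0.0509), and all 13 cell cycle genes rose likewise (13 up, 0 down of 13, median 1.27, p 0.144), MKI67 by 1.92. The RV signature fell (4 up, 39 down of 49, alone 4 and 40, median -0.95, p 0.0183 and up to 0.0509 with 1 library left out).

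OFT cardioids of the ISL1 knockout (WT n = 2) lost their own signature. ADAMTS19 fell (-4.22 ± 0.27, 71.2 against 1340 CPM), LDHA (-3.75 ± 0.24, 195 against 2116 CPM), RSPO3 (-2.94 ± 0.28, 54.2 against 489 CPM), WNT11 (-1.69 ± 0.17, 3.19 against 61.9 CPM) and HAND1 (-1.44 ± 0.16, 8.35 against 65.9 CPM). ID4 rose by 3.33 ± 0.28 (601 against 40.3 CPM), ROBO2 by 2.62 ± 0.24 (208 against 11.5 CPM) and NR2F2 by 2.08 ± 0.36 (160 against 8.34 CPM). CYP1B1 rose by 2.81 ± 0.58 (307 against 1.43 CPM) with an SD of 456 CPM over 3 KO libraries, and did not pass on the 2 groups alone. 1168 genes passed, 463 higher and 705 lower. This count was 537 without WT OFT replicate 1 and 604 without WT OFT replicate 2. It was 762 on the 2 groups alone. The OFT signature (4 up, 34 down of 49, alone 6 and 36, median -1.03, p 0.000516) and the outflow tract list (2 up, 6 down of 8, median -1.36, p 0.00194) fell, WNT5A (-2.90) and SEMA3C (-2.51).

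In Atria cardioids LDHA fell (-3.35 ± 0.22, 181 against 1545 CPM), the mitophagy gene BNIP3 (-2.45 ± 0.28, 82 against 473 CPM), fibrillin FBN2 (-2.41 ± 0.26, 224 against 1023 CPM), RSPO3 (-2.35 ± 0.25, 34.8 against 263 CPM) and TBX3 (-1.26 ± 0.28, 1022 against 2221 CPM). NR2F1 rose by 2.80 ± 0.44 (498 against 61.4 CPM) and HSPA1A by 2.23 ± 0.22 (207 against 22.6 CPM), and ZIC1 stood at 65.1 against 0 CPM. 1225 genes passed, 499 higher and 726 lower. This count was 758 without WT Atria replicate 2 and 809 without WT Atria replicate 3. Atria (3 up, 25 down of 50, alone 4 and 27, median -0.60, p 0.029 and up to 0.054 with 1 library left out) and AVC signatures (4 up, 24 down of 50, alone 6 and 26, median -0.60, p 0.029 and up to 0.054 with 1 library left out) fell. The endoderm list, of which AFP, APOB and FGB are in the AVC signature, summed to 85.3, 108 and 87.1 CPM in WT and 32.0, 32.5 and 17.2 in KO. The knockout effect differed between the 4 types for 1581 genes, including HAND1 (1.49e-07), WNT11 (0.000138) and TNNT2 (0.000583, adjusted p each).

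Mean CPM of TBX5 in the TBX5 libraries at d3.5 follows. LV had 320 (236 to 403, n = 2) in WT and 158 (135 to 192, n = 3) in KO. RV had 2.78 (1.42 to 4.14, n = 2) in WT and 0.427 (0 to 1.28, n = 3) in KO. Atria had 318 (289 to 348, n = 2) in WT and 260 (238 to 272, n = 3) in KO. AVC had 436 (432 to 441, n = 2) in WT and 299 (289 to 310, n = 2) in KO. Means at d9.5 follow. LV had 309 (301 to 316, n = 2) in WT and 388 (330 to 446, n = 3) in KO. RV had 272 (268 to 276, n = 2) in WT and 336 (171 to 604, n = 3) in KO. Atria had 583 (528 to 637, n = 2) in WT and 509 (459 to 555, n = 3) in KO. AVC had 434 (n = 1) in WT and 437 (372 to 514, n = 3) in KO. As for ISL1, 3' tags do not check this deletion.

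In LV progenitors (WT n = 2, KO n = 3 here and in RV and Atria) SERPINE2 fell (-1.84 ± 0.21, 258 against 1140 CPM) and SFRP5 (-1.80 ± 0.14, 6.87 against 137 CPM), and the phosphodiesterase PDE3A rose by 1.31 ± 0.18 (112 against 14.3 CPM). 92 of 8683 genes passed, 34 higher and 58 lower. This count was 33 without KO LV replicate 1 and 22 without WT LV replicate 1. It was 39 on the 2 groups alone. Higher calls were 37% of these and 26.6% with edgeR on recovered reads. In RV progenitors, where TBX5 stood at 2.78 CPM in WT, 63 genes passed, 15 higher and 48 lower, with the endoderm factor FOXA2 at -1.44 ± 0.20, 28.2 against 178 CPM. This count was 5 without WT RV replicate 1, 22 without KO RV replicate 2, 7 without WT RV replicate 2 and 29 without KO RV replicate 3. It was 8 on the 2 groups alone. The endoderm list summed there to 505 and 451 CPM in WT and 93.0, 135 and 105 in KO. Atria progenitors lost NRP2 (-1.75 ± 0.27, 58.9 against 360 CPM), NR2F2 (-1.33 ± 0.20, 128 against 430 CPM) and PPP1R1A (-1.35 ± 0.19, 34.4 against 186 CPM). 99 genes passed, 35 higher and 64 lower. This count was 45 without WT Atria replicate 1, 50 without KO Atria replicate 2 and 16 without WT Atria replicate 2. The endoderm (0 up, 6 down of 7, alone 0 and 7, median -0.93, p 0.00762) and atrial lists (0 up, 2 down of 6, alone 0 and 3, median -0.31, p 0.0158 and up to 0.376 with 1 library left out) fell in Atria. In LV endoderm genes fell too (0 up, 4 down of 7, alone 0 and 6, median -0.64, p 0.0293 and up to 0.135 with 1 library left out), as did the first heart field list (0 up, 2 down of 5, alone 1 and 3, median -0.48, p 0.0293 and up to 0.0913 with 1 library left out, 0.0767 without the filter), while mesenchyme (3 up, 0 down of 6, alone 5 and 0, median 0.79, p 0.0293 and up to 0.135 with 1 library left out) and HOX genes (2 up, 0 down of 5, alone 5 and 0, median 0.69, p 0.0293 and up to 0.216 with 1 library left out, 0.153 without the filter) rose.

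AVC progenitors (2 against 2) lost endoderm transcripts and NR2F2 (-1.41 ± 0.22, 42.2 against 221 CPM). S100A16 fell (-1.97 ± 0.21, 34.3 against 332 CPM), apolipoprotein APOB (-1.92 ± 0.17, 14.6 against 197 CPM) and FOXA2 (-1.65 ± 0.22, 22.7 against 192 CPM), while the sterol enzyme HMGCS1 rose by 1.73 ± 0.25 (693 against 169 CPM). 277 genes passed, 125 higher and 152 lower. This count was 39 without WT AVC replicate 1, 104 without KO AVC replicate 1, 530 without WT AVC replicate 2 and 155 without KO AVC replicate 2. It was 154 on the 2 groups alone. All 7 endoderm genes measured fell (0 up, 7 down of 7, median -1.15, p 0.0224 and up to 0.0939 with 1 library left out). Between the 4 types the effect differed for 35 genes, NR2F2 among them (0.0255). With 1 library left out it ranged from 8 without WT RV replicate 1 to 80 without WT AVC replicate 2. It was 9 without the filter.

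At d9.5 TBX5 knockouts lost the ventricular IRX genes and NPPA. In LV (WT n = 2) FBN2 fell (-3.87 ± 0.29, 49.5 against 1583 CPM), IRX2 (-3.59 ± 0.31, 26.1 against 1002 CPM), the hormone TRH (-3.27 ± 0.22, 9.34 against 532 CPM), IRX4 (-2.68 ± 0.20, 0.511 against 215 CPM) and NPPA (-2.19 ± 0.14, 0.256 against 129 CPM). The chemokine CXCL14 rose by 3.30 ± 0.24 (734 against 22.5 CPM), COL3A1 by 2.83 ± 0.42 (879 against 50.9 CPM) and COL1A2 by 2.3 ± 0.32 (488 against 45.3 CPM). 822 of 9300 genes passed, 363 higher and 459 lower. This count was 415 without KO LV replicate 1, 430 without KO LV replicate 2, 207 without WT LV replicate 1, 1635 without KO LV replicate 3 and 214 without WT LV replicate 2. It was 389 on the 2 groups alone and 436 with the conflicting library as titled. Ventricular genes fell (0 up, 6 down of 9, median -1.80, p 0.00339), IRX1 (-2.67), with the RV (0 up, 18 down of 45, alone 0 and 27, median -0.50, p 0.00339) and LV signatures (1 up, 21 down of 48, alone 2 and 21, median -0.23, p 0.0171 and up to 0.109 with 1 library left out), and the OFT signature rose (18 up, 1 down of 48, alone 23 and 4, median 0.56, p 0.00339). Of the cardiopharyngeal list LHX2 rose by 1.53 (3 up, 0 down of 3, median 1.22, p 0.0296 and up to 0.112 with 1 library left out, 0.0574 without the filter). The endoderm list summed to 450.5 and 200 CPM in WT and 425, 1120 and 154 in KO. In each of the 4 types at d9.5, 2 of 3 KO libraries have lower library numbers than every WT library used. Within the libraries numbered from the first WT on, here the later series and fitted after seeing the data, 663 genes passed in LV, 241 in RV, 2097 in Atria and 1136 in AVC. That fit has 1 KO library per type against 2 WT, or 1 WT in AVC, so its spread comes from the WT groups of LV, RV and Atria.

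In RV (WT n = 2) NPPA was 382 CPM in WT and 0 in all 3 KO libraries. PPP1R14C fell (-3.51 ± 0.14, 1.21 against 457 CPM), MB (-3.22 ± 0.31, 36.5 against 879 CPM), PPP1R12B (-3.20 ± 0.30, 645 against 6078 CPM) and IRX4 (-1.61 ± 0.20, 1.47 against 77.7 CPM), while CNTN5 rose by 2.40 ± 0.24 (377 against 19 CPM) and CCDC80 by 2.17 ± 0.20 (684 against 89.3 CPM). 439 genes passed, 167 higher and 272 lower, and 241 in the later series alone. This count was 276 without KO RV replicate 2, 125 without WT RV replicate 1, 973 without KO RV replicate 3 and 141 without WT RV replicate 2. It was 182 with the conflicting library as titled. Higher calls were 38% of these and 49.9% with edgeR on recovered reads. Ventricular genes (0 up, 8 down of 9, median -1.34, p 0.00339) and the RV (0 up, 22 down of 45, alone 3 and 29, median -0.75, p 0.000733) and LV signatures (4 up, 18 down of 48, alone 6 and 22, median -0.62, p 0.00558) fell, as did the atrial list (0 up, 2 down of 8, alone 0 and 3, median -0.77, p 0.00988 and up to 0.0592 with 1 library left out), while the outflow tract list (2 up, 0 down of 8, alone 5 and 0, median 0.76, p 0.00558) and the OFT signature (16 up, 0 down of 48, alone 31 and 0, median 0.67, p 0.000462) rose. The endoderm list summed to 409 and 442 CPM in WT and 89.2, 12.7 and 15.5 in KO.

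In Atria (WT n = 2) NPPA (0 against 194 CPM) and PPP1R14C (0 against 571 CPM) were at 0 in all 3 KO libraries. TRH fell (-3.88 ± 0.22, 4.58 against 741 CPM), MB (-3.27 ± 0.31, 34.5 against 915 CPM), FHL2 (-2.78 ± 0.21, 24.1 against 511 CPM), TBX3 (-2.28 ± 0.31, 577 against 2960 CPM) and IRX4 (-1.61 ± 0.20, 2.38 against 86.4 CPM). COL3A1 rose by 3.69 ± 0.42 (924 against 12.6 CPM), CNTN5 by 3.56 ± 0.24 (645 against 5.13 CPM) and the protease PLAT by 2.52 ± 0.28 (322 against 10.1 CPM). 2033 genes passed, 953 higher and 1080 lower. This count was 918 without KO Atria replicate 2, 348 without WT Atria replicate 1 and 988 without WT Atria replicate 2. It was 1109 without the filter and 1092 with the conflicting library as titled. The Atria (1 up, 27 down of 48, alone 1 and 33, median -0.96, p 0.00407) and AVC signatures (3 up, 18 down of 48, alone 6 and 24, median -0.75, p 0.0314 and up to 0.0626 with 1 library left out) and the atrial list (0 up, 4 down of 8, alone 0 and 6, median -1.11, p 0.0239 and up to 0.0626 with 1 library left out) fell, and the OFT signature rose (33 up, 0 down of 48, alone 35 and 0, median 0.88, p 0.00124). Endoderm transcripts summed to 870.5 and 532.5 CPM in WT and 95.1, 65.7 and 24.4 in KO.

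AVC at d9.5 had 1 WT library, assumed to vary like the other groups, against 3 KO. PPP1R14C fell (-3.93 ± 0.18, 0.195 against 577 CPM), TRH (-3.63 ± 0.28, 5.26 against 644 CPM), FHL2 (-2.80 ± 0.27, 22.8 against 496 CPM), IRX4 (-2.69 ± 0.25, 0.885 against 224 CPM), NPPA (-2.46 ± 0.18, 0.195 against 163 CPM) and TBX3 (-2.09 ± 0.39, 624 against 2817 CPM). COL3A1 rose by 3.47 ± 0.53 (853 against 13.8 CPM), CNTN5 by 2.88 ± 0.31 (421 against 8.65 CPM) and reelin RELN by 2.56 ± 0.34 (311 against 6.92 CPM). 314 genes passed, 123 higher and 191 lower, and 1136 in the later series alone (1 KO against 1 WT library). It was 590 without the filter and 182 with the conflicting library as titled. With it so used, against its correlations, IRX4 (-1.26), NPPA (-1.20), FHL2 (-1.41), PPP1R14C, TRH (-1.75) and TBX3 (-0.81) no longer passed, nor did IRX4 in RV (-1.61). No TBX5 d9.5 list was rerun with it as titled or on the later series alone. The OFT signature (19 up, 0 down of 48, alone 33 and 0, median 0.97, p 0.00035) and the outflow tract list (2 up, 0 down of 8, alone 4 and 0, median 0.77, p 0.0178) rose, and the Atria signature (1 up, 19 down of 48, alone 3 and 23, median -0.61, p 0.00899) and ventricular list (0 up, 7 down of 9, alone 0 and 8, median -1.09, p 0.0125) fell. Endoderm sums were 695 CPM in WT and 130, 255 and 1096 in KO. Between types 42 genes differed, NPPA among them (0.0158), and 894 in the later series alone. With 1 library left out it ranged from 14 without WT LV replicate 2 to 71 without KO AVC replicate 3. This count was 453 without the filter, 20 with edgeR on recovered reads and 16 with the conflicting library as titled. MALAT1 and KCNQ1OT1, noncoding RNAs chosen after the values were seen, stood at 17100 to 31500 and 545 to 927 CPM in the KO libraries before the later series against 3400 to 9210 and 229 to 399 in WT.

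FOXF1 was low in most FOXF1 libraries. Mean CPM at d3.5 follows. RV had 2.67 (1.92 to 3.42, n = 2) in WT and 2.64 (1.72 to 3.56, n = 2) in KO. FHF had 12.3 (8.92 to 15.7, n = 2) in WT and 4.33 (n = 1) in KO. Atria had 130 (122 to 138, n = 2) in WT and 89.5 (85.8 to 93.2, n = 2) in KO. Means at d9.5 follow. FHF had 7.77 (6.19 to 9.73, n = 3) in WT and 7.3 (4.59 to 10, n = 2) in KO. RV had 6.93 (4.39 to 9.98, n = 3) in WT and 5.51 (4.75 to 6.21, n = 3) in KO. Atria had 11.4 (8.57 to 15.7, n = 3) in WT and 9 (8.17 to 9.52, n = 3) in KO. Here too 3' tags do not check the deletion.

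FHF progenitors (WT n = 2, KO n = 1, assumed to vary like the other groups) lost NPPB (-2.3 ± 0.19, 75.1 against 500 CPM), PPP1R1A (-1.50 ± 0.17, 5.25 against 56.1 CPM) and PPP1R14C (-1.36 ± 0.16, 59 against 198 CPM). ZIC1 (2.25 ± 0.22, 81.9 against 1.08 CPM), HSPA1A (1.72 ± 0.14, 188 against 34.3 CPM) and the imprinted NNAT (1.70 ± 0.16, 547 against 140 CPM) rose. 174 of 10293 genes passed, 99 higher and 75 lower. This count was 49 without WT FHF replicate 1 and 64 without WT FHF replicate 2. It was 581 without the filter and 514 on the 2 groups alone. Higher calls were 56.9% of these and 70.3% with edgeR on recovered reads. RV progenitors (2 against 2) gained ZIC1 (2.69 ± 0.18, 110 against 0.16 CPM), SPINK5 (1.51 ± 0.15, 57.3 against 4.31 CPM), CCBE1 (1.08 ± 0.14, 64.5 against 15.8 CPM) and HSPA1A (1.04 ± 0.11, 80.1 against 22.9 CPM) and lost the phosphatase INPP5F (-1.05 ± 0.11, 12.6 against 55.8 CPM), RELN (-1.05 ± 0.13, 33.5 against 105 CPM), DACH1 (-0.97 ± 0.10, 14 against 54.3 CPM) and MEG3 (0 against 84.2 CPM). 28 genes passed, 16 higher and 12 lower. This count was 231 without WT RV replicate 1 and 49 without WT RV replicate 2. It was 7 without the filter and 2 on the 2 groups alone. On these 2 groups alone, of the genes named MEG3 passed while ZIC1, SPINK5, CCBE1, HSPA1A, INPP5F, RELN and DACH1 did not. No list was called in FHF or RV.

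In Atria progenitors, with the highest FOXF1 (130 CPM in WT), TECRL rose by 2.25 ± 0.14 (180 against 13.3 CPM), the calcium pump regulator PLN by 1.85 ± 0.11 (109 against 9.39 CPM), LRAT by 1.78 ± 0.18 (82.1 against 5.47 CPM) and ZIC1 by 2.08 ± 0.18 (63.7 against 0.363 CPM). LDHA fell (-1.93 ± 0.20, 197 against 839 CPM), GNG2 (-1.51 ± 0.17, 27.7 against 135 CPM), DACH1 (-1.50 ± 0.10, 37.4 against 163 CPM) and NR2F2 (-1.09 ± 0.14, 231 against 519 CPM). Without the expression filter GNG2 and NR2F2 did not pass. 241 genes passed (2 against 2), 111 higher and 130 lower. This count was 44 without WT Atria replicate 1, 80 without KO Atria replicate 1, 43 without WT Atria replicate 2 and 50 without KO Atria replicate 2. It was 69 without the filter and 1008 on the 2 groups alone. The called lists, glycolysis and hypoxia (0 up, 6 down of 11, median -0.68, p 0.0424 and up to 0.143 with 1 library left out, 0.0699 without the filter), atrioventricular canal (3 up, 0 down of 9, alone 5 and 0, median 0.43, p 0.0495 and up to 0.143 with 1 library left out, 0.0699 without the filter) and the aSHF signature (1 up, 6 down of 50, alone 1 and 10, median -0.23, p 0.0424 and up to 0.143 with 1 library left out, 0.0699 without the filter), did not hold with each library left out. Between types 72 genes differed, including NR2F2 (0.0166). With 1 library left out it ranged from 8 without KO Atria replicate 1 to 320 without WT RV replicate 1. It was 5 without the filter and 46 with edgeR on recovered reads.

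At d9.5 FHF cardioids (WT n = 3, KO n = 2) lost LDHA (-2.29 ± 0.29, 450 against 2197 CPM) and BNIP3 (-1.75 ± 0.23, 130 against 515 CPM) and gained ZIC1 (2.35 ± 0.21, 84.9 against 1.38 CPM), SPINK5 (2.09 ± 0.28, 94.9 against 3.92 CPM) and HSPA1A (1.69 ± 0.17, 142 against 21.4 CPM). 100 genes passed, 51 higher and 49 lower. This count was 21 without KO FHF replicate 1, 56 without WT FHF replicate 2, 21 without KO FHF replicate 2 and 49 without WT FHF replicate 3. It was 264 on the 2 groups alone. The endoderm list summed to 271, 67.8 and 222 CPM in WT and 67.75 and 45.9 in KO. RV cardioids (3 against 3) lost XIRP2 (-1.53 ± 0.21, 16.6 against 97.1 CPM), NPR3 (-1.52 ± 0.16, 7.83 against 68.7 CPM) and ABRA (-1.07 ± 0.15, 33.2 against 103 CPM), and gained ZIC1 (2.42 ± 0.19, 97.5 against 1.54 CPM), SPINK5 (1.91 ± 0.25, 83.2 against 4.3 CPM), HSPA1A (1.77 ± 0.15, 182 against 29.9 CPM) and IRX4 (1.38 ± 0.17, 71.1 against 11.3 CPM). 34 genes passed, 19 higher and 15 lower. This count was 20 without WT RV replicate 1, 22 without WT RV replicate 2 and 22 without KO RV replicate 3. Higher calls were 55.9% of these and 69.8% with edgeR on recovered reads. In RV the endoderm list summed to 44.8, 57.6 and 103 CPM in WT and 34.3, 40.0 and 29.8 in KO.

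Atria cardioids (3 against 3) lost NR2F2 (-1.49 ± 0.19, 128 against 445 CPM) and GPR37 (-1.19 ± 0.14, 18.7 against 81.6 CPM), and gained IRX4 (1.68 ± 0.17, 101 against 12.3 CPM), ZIC1 (2.24 ± 0.19, 71.7 against 0.892 CPM) and HSPA1A (2.01 ± 0.15, 169 against 20.4 CPM). 98 genes passed, 49 higher and 49 lower. This count was 956 without WT Atria replicate 1, 27 without KO Atria replicate 1, 47 without WT Atria replicate 2, 1287 without KO Atria replicate 2, 61 without WT Atria replicate 3 and 36 without KO Atria replicate 3. It was 14 on the 2 groups alone. KO replicates 1 and 3 and WT replicate 1 stood apart, with KCNQ1OT1 at 19.9, 23.1 and 59.0 CPM against 641, 1017 and 683 in the other 3. Without these 3 libraries, an alternative added after seeing the data, 12 genes passed in Atria, 164 in FHF and 60 in RV. Atria then has 1 KO against 2 WT libraries, the lone KO assumed to vary like the other groups, and NR2F2 (-1.27) did not pass. Fitted on the 2 groups alone, NR2F2 did not pass. Between types 12 genes differed, among them IRX4 (0.00739) and NR2F2 (0.0387), and 10 without the 3 libraries. With 1 library left out it ranged from 0 without KO FHF replicate 2 to 57 without KO Atria replicate 2. It was 2 with edgeR on recovered reads. No list was called at d9.5.

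The ISL1 and FOXF1 knockouts shared genes. SPINK5, ZIC1 and HSPA1A rose and MEG3, chosen with SLITRK4 after the values were seen, fell in all 8 ISL1 and all 6 FOXF1 comparisons. In ISL1 WT libraries ZIC1 stood at 0.207 CPM at d3.5 and 0.104 at d9.5, against 104 and 83.2 in KO, and in the 99 time-course libraries at 0.0362. MEG3 went from 42.2 to 0.0808 CPM at d3.5 in the ISL1 series and from 42.9 to 0.0547 in the FOXF1 series, and was 0.556 (at most 5.4) in the time course. HSPA1A rose from 19.1 to 108 CPM (ISL1) and from 25.2 to 104 (FOXF1) at d3.5, and was 67.3 in the time course. In TBX5 WT it was 34.6 CPM at d3.5 and 102 at d9.5, against 101 and 135 in KO. The close paralogue HSPA1B was 18.9 and 18.3 CPM in ISL1 WT and KO at d3.5. MEF2C, TRIM4 and UBLCP1 fell and SOX11, SLITRK4, BCOR, FSIP2 and ZNF493 rose in all 8 ISL1 comparisons, NFIA rose in all 6 FOXF1 ones, and SLITRK4 was the 1 gene higher in all 8 TBX5 comparisons. In RV at d3.5, ISL1 and FOXF1 knockouts shared 13 rises and 11 falls against 0.221 and 0.224 expected by chance, and at d9.5 10 rises and 13 falls against 1.95 and 1.71. ISL1 and TBX5 knockouts shared 61 rises and 165 falls in RV at d9.5 against 18.3 and 34.7.

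**Figure D4:**
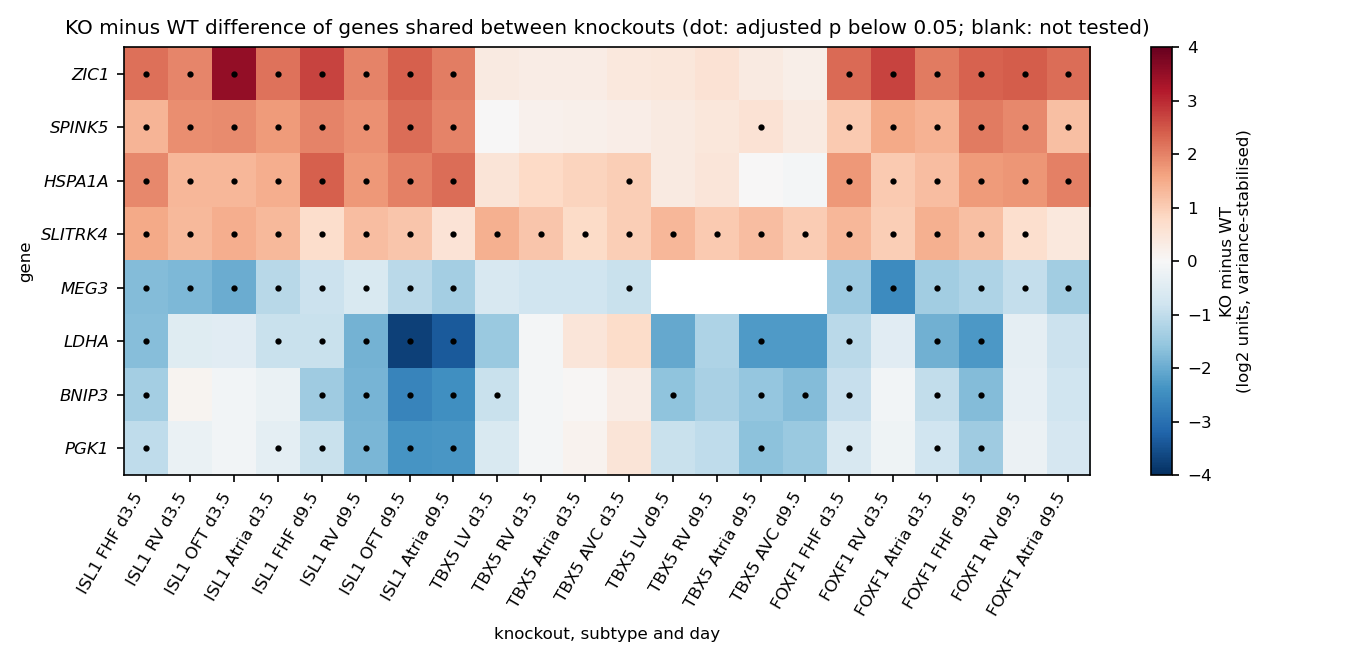
Differences between KO and WT of 8 genes shared between knockouts, chosen after the values were seen. ZIC1 ranged from 0.104 CPM in ISL1 WT to 83.2 in ISL1 KO at d9.5.

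Over the 22 knockout comparisons the fixed lists were called, higher then lower, as follows. Outflow tract 2 and 3, HOX 2 and 0, atrial 0 and 4, ventricular 0 and 3, glycolysis and hypoxia 0 and 3, endoderm 0 and 3, first heart field 0 and 2, anterior second heart field 0 and 1, calcium handling 0 and 1. Posterior second heart field, BMP targets, atrioventricular canal, mesenchyme and cardiopharyngeal lists had 1 and 0 each. Not called, with the smallest p in brackets, were sarcomere (0.0509), retinoic acid (0.144), cell cycle (0.144), fatty acid oxidation (0.159), endothelial (0.212), WNT targets (0.226), p53 targets (0.25), pluripotency (0.38), neural (0.562), epicardial (0.618) and NODAL (0.756).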

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

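A test of the difference between cardioid types within each knockout, fixed before the data were examined, marked the results below. The knockout effect differed between types for 735 genes in ISL1 at d3.5, 1581 in ISL1 at d9.5, 35 in TBX5 at d3.5, 42 in TBX5 at d9.5, 72 in FOXF1 at d3.5 and 12 in FOXF1 at d9.5.

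Among the 10 fixed genes, adjusted p in the ISL1 series at d3.5 was 8.88e-10 for ISL1, 3.28e-06 for TBX5, 0.000325 for TBX3, 0.00407 for FOXF1, 0.00786 for NPPA and 0.00822 for NR2F2. ISL1 transcript itself was higher in KO than in WT in FHF (227 against 89.7 CPM) and lower in Atria (93.0 against 161 CPM) at d3.5. At d9.5 it was 1.49e-07 for HAND1, 0.000138 for WNT11, 0.000583 for TNNT2, 0.00156 for NR2F2, 0.00249 for TBX3, 0.00403 for ISL1 and 0.00688 for NPPA. HAND1 was higher in FHF and lower in OFT in the ISL1 knockout. In the TBX5 series NR2F2 (0.0255) at d3.5 and NPPA (0.0158) at d9.5 differed. In the FOXF1 series NR2F2 differed at d3.5 (0.0166) and d9.5 (0.0387), and IRX4 at d9.5 (0.00739).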

How the results depend on the processing

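Added after seeing the data were edgeR on recovered reads, the uses of the library with conflicting labels, the later series alone, the fit without 3 Atria libraries and the alternatives of the list tests. The cause of a change was not tested. In all, 44 counts were run under 654 alternatives, 1543 gene results under 10235 and 168 lists under 771.

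Without the expression filter counts were 7 (d1.5 LV minus SHF), 44 (AVC minus SHF), 62 (LV minus AVC), 9 and 453 (TBX5 interaction d3.5 and d9.5), 1109 (TBX5 Atria d9.5), 590 (TBX5 AVC d9.5), 581, 7 and 69 (FOXF1 FHF, RV and Atria d3.5) and 5 (FOXF1 interaction d3.5). With the replicate block they were 1, 28 and 19 at d1.5 (LV minus SHF, AVC minus SHF, LV minus AVC), 258, 150 and 503 (TBX5 LV, Atria, AVC d3.5), 98 (interaction), 1661, 1477, 3561 and 1468 (TBX5 LV, RV, Atria, AVC d9.5), 100 (interaction), 190, 52 and 228 (FOXF1 FHF, RV, Atria d9.5) and 26 (interaction). Not every pair of same-number libraries passed a correlation of 0.1, so numbers were not taken as pairs. Their mean correlation was 0.011 to 0.121 by day in the time course, 0.068 and 0.19 in TBX5 and 0.053 and 0.175 in FOXF1 (d3.5, d9.5). Libraries closest to their own number were 8 of 9 at d1.5 and 12 of 15 at d14, 7 to 9 on other days, 7 of 19 and 14 of 18 in TBX5, and 10 of 10 and 14 of 17 in FOXF1. In LV, RV and Atria of TBX5, library numbers set WT 1 next to KO 2 at d3.5 and next to KO 3 at d9.5, so the block there need not join libraries made together, and its counts and list losses do not test such sets. The ISL1 titles carry no replicate numbers, the numbers in its column headers were not used as pairs, and this block was not run there.

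A library series term gave 36 for AVC minus SHF, and DESeq2 16 for LV minus AVC. A fit on all 99 libraries gave 11 (AVC minus SHF), 1733, 1645 and 1364 (d9.5 LV, AVC, Atria) and 905 (LV minus RV). Fits of only the 2 groups compared gave 143, 1240 and 762 (ISL1 Atria d3.5, FHF d9.5, OFT d9.5), 39, 8, 154 and 389 (TBX5 LV, RV, AVC d3.5, LV d9.5), and 514, 2, 1008, 264 and 14 (FOXF1 FHF, RV, Atria d3.5, FHF and Atria d9.5). On recovered reads edgeR gave 20 (TBX5 interaction d9.5), 46 and 2 (FOXF1 interaction d3.5 and d9.5). It moved the share of higher calls from 37% to 26.6% (TBX5 LV d3.5), 38% to 49.9% (TBX5 RV d9.5), 56.9% to 70.3% (FOXF1 FHF d3.5) and 55.9% to 69.8% (FOXF1 RV d9.5).

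With the conflicting library as titled, TBX5 d9.5 counts were 436 (LV), 182 (RV), 1092 (Atria), 182 (AVC) and 16 (interaction), and in AVC MYH6 (1.09), MYOM1 (0.27) and PRDM16 (0.01) changed direction. The later series alone gave 241 (RV), 1136 (AVC) and 894 (interaction), with 1 KO library per type. Without the 3 Atria libraries FOXF1 d9.5 gave 164 (FHF), 60 (RV) and 12 (Atria).

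Leaving out each library gave 0 to 1 (d1.5 LV minus SHF), 5 to 15 (AVC minus SHF), 1 to 18 (LV minus AVC), 753 to 1209 (d3.5 AVC) and 631 to 881 (d4.5). At d9.5 it gave 619 to 1484 (LV), 607 to 1363 (RV), 1081 to 1915 (OFT), 540 to 1432 (AVC), 407 to 1073 (Atria) and 354 to 596 (LV minus RV). For ISL1 d9.5 it gave 758 to 1213 (Atria), 452 to 724 (FHF) and 537 to 1092 (OFT). For TBX5 d3.5 it gave 22 to 87 (LV), 5 to 69 (RV), 16 to 80 (Atria), 39 to 530 (AVC) and 8 to 80 (interaction), and at d9.5 207 to 1635 (LV), 125 to 973 (RV), 348 to 2033 (Atria, 2033 being the main count) and 14 to 71 (interaction). For FOXF1 d3.5 it gave 49 to 64 (FHF), 20 to 231 (RV), 43 to 80 (Atria) and 8 to 320 (interaction), and at d9.5 21 to 80 (FHF), 20 to 34 (RV), 27 to 1287 (Atria) and 0 to 57 (interaction).

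Other counts stayed within 1.5 times. With libraries left out, 170 of 195 time-course counts did, 88 of 94 for ISL1, 34 of 77 for TBX5 and 11 of 54 for FOXF1. The 77 count the unused conflicting library too, in LV, RV and Atria d9.5. Gene results, called or not, held for 757 of 908 in the time course, 277 of 298 in ISL1, 151 of 232 in TBX5 and 83 of 105 in FOXF1. List calls held for 90 of 119, 15 of 20, 15 of 26 and 0 of 3. The replicate block ended 18 of 119 list calls in the time course, 9 of 26 in TBX5 and 3 of 3 in FOXF1. In the knockouts these are, with p, mesenchyme (0.0575), endoderm, first heart field and HOX (0.0975 each) in TBX5 LV d3.5, endoderm in AVC d3.5 (0.0509), cardiopharyngeal in LV d9.5 (0.0833), atrial in Atria d9.5 (0.0626), ventricular and outflow tract in AVC d9.5 (0.0523 each), and the 3 lists of FOXF1 Atria d3.5 (0.0808 each). Fits without the filter ended 21 of 119, 2 of 20 (ISL1), 3 of 26 and 3 of 3, and the library series term 8 of 119. Of the time-course lists given with values, the block ended 0 and the filter 1, ventricular in aSHF (0.108). Groups of 1 or 2 libraries and the depth of the shallowest ISL1 library, 437482 reads, limit what can be called.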

Other observations

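All tests in this part were chosen after the results were seen, and the patterns were found on the same libraries.

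Genes shared by the ISL1 and FOXF1 knockouts are the first pattern. Of 9045 genes tested in both, 21 changed the same way in at least 4 of 8 ISL1 and 3 of 6 FOXF1 comparisons. Against 0.47 expected, this argues against chance. Of them 10 were higher against 0.219 and 11, LDHA, PGK1, HK2, BNIP3 and FAM162A among them, lower against 0.251. The authors' normalization is argued against too, since 220 of the 228 calls of these 21 genes in ISL1 and FOXF1 held with edgeR on recovered reads. Loss of the targeted gene stays open. In FOXF1 RV d3.5 (WT 2.67 CPM of FOXF1) 10 of 15 ISL1-wide genes changed the same way (0.02 by chance). In TBX5 RV d3.5 4 of 14 did (0.051). Earlier loss was not tested. On the 2 FOXF1 groups alone few calls held. A difference between KO and WT lines other than the targeted gene stays open, since line and KO cannot be told apart here. In 8 TBX5 comparisons, 84.6% of ISL1-wide genes by comparison had the same sign (50% expected) and 33 of 104 passed. ZIC1 passed in 0 of 8, but stood at 42.5 (d3.5) and 31.8 CPM (d9.5) in TBX5 WT.

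Endoderm transcripts in LV and AVC at d9.5 are the second pattern. Of 12 gene by type pairs 11 were higher, with AFP at 438.5 CPM in LV and 291.4 in AVC and APOA2 at 67.17 and 35.01. This count repeats the list calls, so it does not decide whether endoderm-type cells are the source. A single library is argued against, since 9 of 10 calls held with each library left out. No count of such cells was made, and how many of the listed genes cardiac cells also express was not assessed.

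Calls of the TBX5 knockouts at d9.5 are the third pattern, since 8 KO libraries have lower library numbers than the other 4 KO and all 7 WT, which are called the later series here although no label names one. Within the later series the MALAT1 ratio of KO to WT was 2.31 as a geometric mean over 4 types (0.874 in LV, 1.66 in RV, 4.97 in Atria, 3.94 in AVC). With 1 KO library each, series and knockout cannot be told apart for MALAT1 and KCNQ1OT1. Of genes called without KO replicate 3 and WT replicate 2, the difference between those 2 libraries had the same sign for 78.7% in LV, 67.2% in RV and 97.8% in Atria, against 59.6%, 53.9% and 80.3% of all genes. Part of the LV and RV calls could come from the lower-numbered libraries, and the single later KO library per type keeps this open.

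Other splits of the libraries were counted. In comparisons of more than 2 groups the libraries of all groups were divided anew, so groups that differ add to the spread of other splits and can lower their counts. For induction (5866 genes, 5907 in another split) and d3.5 Atria (1343 and 2687), 2 of 100 splits were as large, counting the real one, and another division gave more. No other split reached the real count for d3.5 LV (1 of 100, 3780 genes and at most 967 in another), aSHF (2090 and 849), AVC (1137 and 137), d9.5 LV (1038 and 3), RV (1099 and 31), OFT (1664 and 2), AVC (990 and 342), Atria (805 and 13), and d14 minus d7.5 (1 of 25, 6867 and 0). Given that lowering, this does not exclude chance for 1 type. For the ISL1 interaction at d3.5, divided within types that hold KO and WT, 1 of 100 was as large (735 and 600), with the same limit. With 10 splits no share under 0.05 can be had, and the real and highest other counts were 0 and 1 (LV minus SHF, 10 as large), 18 and 0 (AVC minus SHF), 7 and 1 (LV minus AVC), 987 and 0 (d4.5) and 573 and 0 (LV minus RV). For ISL1 they were 1003 and 63 (FHF), 323 and 1 (RV), 516 and 0 (OFT) and 224 and 0 (Atria) at d3.5, and 789 and 0 (FHF), 2490 and 0 (RV) and 1225 and 0 (Atria) at d9.5. For FOXF1 at d9.5 they were 34 and 1 in RV and 98 and 3662 in Atria, where the split that sets KO replicates 1 and 3 with WT replicate 1 apart gave more.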
